A study of Mus musculus with 6 samples.

How the data were processed

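RNA was sequenced from CD1d tetramer-sorted thymic NKT cells of the P1 fraction, with 3 WT and 3 DKO libraries. Per the labels' protocols, polyadenylated RNA was taken through a published amplification method for small numbers of cells and an indexed Illumina kit. Per the submitters' processing notes, Bowtie and the mm9 build were used, and their versions and settings, the annotation and the counting method are not given in the sources used here. The authors deposited RPKM values for 10772 genes in 6 library columns, 1 per library, with a gene length, and no value was averaged over libraries. Every row exceeded RPKM 3 in at least 2 libraries, a filter found by testing the file. Because of that filter, genes silent in one group and expressed in a single library of the other were not seen.

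RPKM multiplied by gene length was a whole multiple of a library-specific step, within 0.05 of a whole number, for 99.6% to 100.0% of values per library. The steps gave implied totals of 32.4 M, 7.2 M and 5.0 M reads for WT replicates 1 to 3 and 34.4 M, 7.1 M and 6.4 M for DKO replicates 1 to 3, of which 75.6% to 80.6% fell in listed genes. At the median gene length 1 read was worth RPKM 0.0163, 0.0729 and 0.105 in the WT libraries and 0.0153, 0.0745 and 0.0818 in the DKO libraries, and a count of 0 allows up to 3 reads. Reads after amplification are not independent molecules, so such limits cover counting error only. No count model was run, because the deposited unit is RPKM, and voom on the recovered reads, a weighted linear model, served only as an alternative. Genes without a symbol (540 rows) kept their identifier. Identifiers were matched to GENCODE M21 for names only, with 9918 of 10772 found. That annotation belongs to another build than mm9, so no coordinates are given. Where symbols differed the current symbol is printed.

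Rows sharing a symbol were reduced to the row with the highest mean, which left 10755 genes. Genes with RPKM of at least 1 in at least 3 libraries were tested (10694 genes, 61 left out). Differences were tested on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, 4 residual degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. The median standard error of a log2 fold change was 0.43. Sex was tested with genotype in the model, and the interaction with 2 residual degrees of freedom. Levels are means with SD over 3 libraries, and the deleted genes were compared by an exact two-sided permutation test. Genes of 27 fixed lists (357 of 559 listed genes were in the table) were tested by camera with a preset correlation of 0.01, where at least 5 genes were tested, with camera using an estimated correlation and fry beside it. Counts adjusted over the list alone treat each list as its own family. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the values and figures.

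The test was tried on simulated data drawn from the real genes' levels and depths, in 5 sets of 200 changed genes among 10755 genes, of which on average 10727 were tested. For DKO against WT it recovered 10.8% of 2-fold, 58.8% of 4-fold, 85.2% of 8-fold and 91.2% of 16-fold changes, and 4.7% of calls were false. A planted list was found and 0 of 199 random lists of 30 genes were called. Simulated genes varied independently of each other, while the estimated correlation in the real cell cycle list was 0.384. The random lists therefore do not check the preset correlation of 0.01.

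Groups, tests, gene lists, the rule for named genes and the alternatives in the closing section were fixed from the labels before the values were seen, except 3 alternatives chosen after seeing the data (voom on the recovered reads, reads thinned to equal implied totals, and the 4 shallower libraries). The rule named Kdm6a, Kdm6b and Uty, the 12 genes of each direction with the smallest p and groups that did not overlap where fewer than 10 passed, the 4 genes with the smallest p on each list, and the first 6 and 4 for sex and interaction. Other genes named (Il2rb, S1pr1, Egr1, Irf4, Nr4a1, Mki67, Top2a, H2-Ab1, Klrb1c, Zbtb16, Thy1, Cd163l1, Hist1h3a, Trac, Trbc1, Trbc2 and Traj18) were chosen after their values were seen.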

Results

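RNA was sequenced from natural killer T (NKT) cells sorted from mouse thymus. NKT cells are T cells with a nearly invariant alpha-beta receptor that recognises lipids presented by CD1d. The sorted fraction, called P1 in the labels, bound a CD1d tetramer loaded with the lipid PBS-57 and lacked CD24, NK1.1 and CD44 at the surface. The series is titled for the role of UTX and JMJD3 in NKT development. These proteins, encoded by Kdm6a and Kdm6b, remove methyl groups from lysine 27 of histone H3. The comparison was between 3 wild-type (WT) libraries and 3 libraries labelled DKO, each group holding 2 female libraries and 1 male library on a mixed strain background. Values were RPKM (reads scaled to gene length and to the library's mapped reads) for 10772 rows, each above RPKM 3 in at least 2 libraries, so genes near silence in nearly all libraries were not measured. Read totals implied by the RPKM steps were 32.4 M, 7.2 M and 5.0 M for WT replicates 1 to 3 and 34.4 M, 7.1 M and 6.4 M for DKO replicates 1 to 3, so replicate 1 of each genotype formed a deeper pair. Replicates 1 and 2 of each genotype were female and replicate 3 was male. The labels do not say whether libraries of one genotype came from separate animals, so p-values measure the spread between these libraries. The descriptions number both female DKO samples 2, while their titles number them 1 and 2, and the titles were followed here. No pair of libraries was identical. DKO libraries correlated with each other at 0.857 to 0.876 on the log2 scale, below the 0.913 to 0.954 among WT libraries and the highest values between genotypes (0.834 to 0.903).

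The deleted genes were examined first. Kdm6a (ENSMUSG00000037369) was at RPKM 4.62 ± 2.57 (SD, n = 3) in WT and 4.59 ± 0.937 (SD, n = 3) in DKO, a difference within the spread (exact two-sided permutation test, p = 0.8). Kdm6b (ENSMUSG00000018476) was at 2.80 ± 1.05 in WT and 1.66 ± 0.834 in DKO (SD, n = 3 each), and the groups overlapped (exact permutation p = 0.2). With 3 libraries against 3 the smallest p this test can give is 0.1. The Kdm6a reads behind these values were 1356, 209 and 58 in the WT libraries and 1015, 222 and 135 in the DKO libraries. A value over a whole gene does not separate deleted exons from kept ones, so it does not check the genotype labels, and DKO below means the libraries labelled DKO. Uty, the Y-linked relative of Kdm6a, had no row in the table. The Y-linked gene Eif2s3y was at RPKM 58.3 and 47.0 in the male WT and DKO libraries and at most 0.078 in the female ones, as their labels state.

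The DKO cells had much lower levels of genes of the T cell receptor gamma locus and of S100a4, S100a6, Lgals1 and Anxa2. S100a4, a calcium-binding protein, fell from RPKM 768 ± 389.8 to 17.5 ± 17.9 (SD, n = 3 each), a log2 change of -5.67 ± 0.61 (SE, adjusted p = 0.0124). S100a6, a close relative, fell from 373 ± 115 to 43.9 ± 14.7, and Lgals1, which encodes galectin-1, from 729 ± 231 to 107 ± 52.5. Anxa2, encoding the membrane-binding protein annexin A2, fell from 239.5 ± 58.3 to 46.8 ± 21.8 (log2 change -2.39, adjusted p = 0.0461). Amigo2, a cell adhesion protein, was the 1 gene that rose, from 0.289 ± 0.104 to 13.7 ± 0.717 (log2 change 3.51 ± 0.46, adjusted p = 0.0287).

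**Figure D1:**
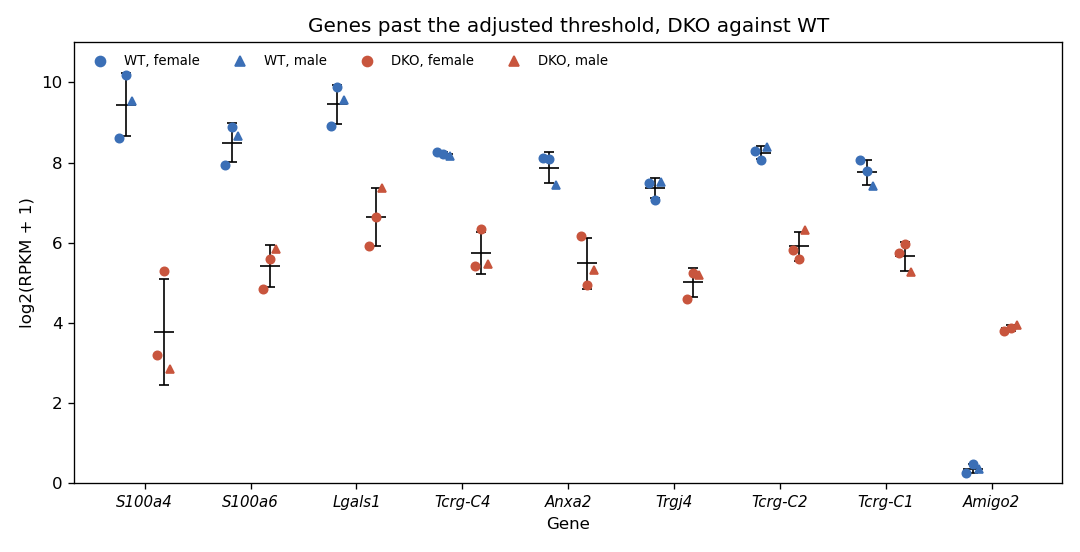
Levels of the 9 genes past the adjusted threshold, as log2(RPKM + 1), with 1 point per library (circles female, triangles male), and the group mean and SD in black. The WT and DKO libraries did not overlap for any of the 9 genes, with 8 lower and 1 higher in DKO.

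The gamma locus genes fell together. Tcrg-C2, a gamma constant gene (Gm16603 in the file), fell from RPKM 305 ± 35.1 in WT to 60.6 ± 16.1 in DKO (log2 change -2.33 ± 0.24 SE, adjusted p = 0.0124). Tcrg-C4 fell from 296 ± 12.7 to 55.2 ± 22.2, Trgj4 from 165 ± 27.1 to 32.0 ± 7.53, and Tcrg-C1 from 219 ± 47.9 to 50.8 ± 12.3. Trgj2 was at 68.2 ± 8.70 in WT and 10.6 ± 5.47 in DKO and did not pass (adjusted p = 0.0507). Some gamma constant genes are near-identical copies, so the authors' counting could have moved reads between those copies. Summed over the 10 listed rows of the locus, which such sharing leaves unchanged, reads per 1 M were 539 ± 36.2 in WT and 108 ± 9.4 in DKO (SD, n = 3 each).

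These 9 genes were all that passed limma's moderated test on log2(RPKM + 1) at a Benjamini-Hochberg adjusted p of 0.05 among 10694 genes tested, 8 lower and 1 higher. At an unadjusted p of 0.05 there were 871 lower and 308 higher genes, against about 535 in all by chance. By size alone, 532 genes were at least 2-fold lower and 187 at least 2-fold higher with groups that did not overlap. The median of all genes was shifted by -0.11 log2 units in DKO, and changes are to be read against that shift. With quantile normalization the 9 calls became 7 lower and 3 higher, and the size counts 409 lower and 329 higher, and with median log2 ratio scaling the size counts were 442 lower and 275 higher. Of 23 alternatives the call was lost in 5 for S100a6, 6 for S100a4, 7 each for Tcrg-C2, Tcrg-C4 and Trgj4, 9 each for Tcrg-C1 and Lgals1, 12 for Amigo2 and 14 for Anxa2. Leaving out any 1 library ended the Amigo2 call (adjusted p 0.0695 to 0.178), and the Anxa2 call ended with a pseudocount of 0.5 (0.0559), a fixed sum (0.0509) and quantile normalization (0.0542). The number of calls was 2 without WT replicate 1, 0 without WT replicate 2, 0 without WT replicate 3 and 24 with array weights, and voom on the recovered reads, an alternative chosen after seeing the data, called 0 genes with 1677 at an unadjusted p of 0.05. In the deeper pair and in the 4 shallower libraries taken apart, the log2 change of S100a4 was -5.41 and -5.80 and that of Amigo2 3.55 and 3.49, with directions fixed by groups that do not overlap.

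Genes next in rank that did not pass give values of the same kind. Among those lower in DKO, Cd7, a receptor on T and NK cells, was at RPKM 59.7 ± 20.7 in WT and 11.6 ± 0.743 in DKO (adjusted p just above 0.05). Perp, a p53-responsive membrane protein, was at 15.1 ± 6.74 and 0.215 ± 0.187, and Shmt2, a mitochondrial enzyme of serine and glycine metabolism, at 90.4 ± 13.8 and 29.4 ± 0.933 (SD, n = 3 each). Among those higher in DKO, Sostdc1, an antagonist of BMP signalling, was listed at 0 in the 3 WT libraries and at 17.0, 19.5 and 6.65 in the DKO libraries. Txnip, a thioredoxin-binding protein that restrains glucose uptake, was at 30.1 ± 9.47 in WT and 135 ± 43.3 in DKO, and Satb1, a chromatin organiser of developing T cells, at 117 ± 28.0 and 335 ± 79.4. Btg1, an antiproliferative gene, was at 56.3 ± 5.99 and 144 ± 44.8, and Dgka, a diacylglycerol kinase that dampens receptor signalling, at 107 ± 6.96 and 228 ± 40.5. Tnfrsf4 (OX40) was at 9.45 ± 5.19 and 50.3 ± 28.8. Catsperd, Pla2g7, Tceal3, Miip and Tmem273 completed the 12 highest in rank, with log2 changes from 1.71 for Miip to 3.10 for Tmem273 and adjusted p from 0.0923 for Catsperd to 0.1466 for Tmem273.

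**Figure D2:**
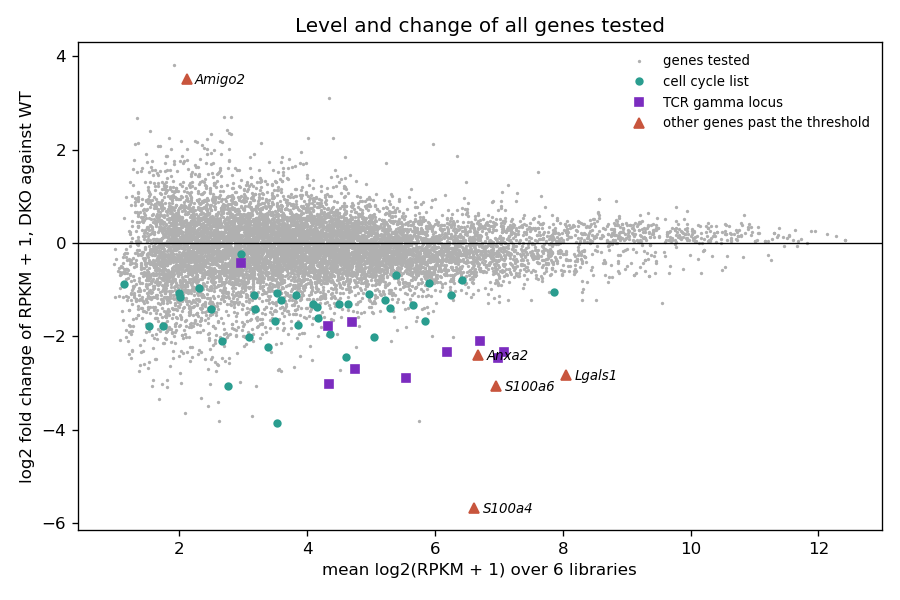
Log2 fold change of RPKM + 1 in DKO against WT (vertical axis) against the mean log2(RPKM + 1) over the 6 libraries (horizontal axis), with 1 point per gene tested (10694). The 38 genes of the cell cycle list and the rows of the gamma locus lie below 0, and S100a4 lies lowest at -5.67.

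Gene lists for NKT subsets, cell programmes and other cell types had been fixed beforehand, and 20 lists with at least 5 genes tested were compared by camera. With its preset correlation, 6 lists were lower and 4 higher in DKO at an adjusted p of 0.05. With the correlation estimated from these libraries, 0 of the 20 passed, and fry, which asks whether a list's own genes move one way, called 3 (NKT1 and maturation, CD8 T cell, and gamma-delta and NK).

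Genes of the cell cycle were lower in DKO as a group. Of 40 listed, 38 were tested, and the log2 change lay below 0 in 38 of the 38, with a median of -1.32. The groups did not overlap in 21 of the 38, and Mki67 and Top2a were among those that overlapped. Mki67 was at RPKM 46.4, 10.8 and 7.42 in the WT libraries and 14.8, 1.465 and 11.95 in the DKO libraries. Adjusted over the list alone 21 fell, and over all genes 0 passed. Cdc20, an activator of the anaphase-promoting complex, was at RPKM 22.2 ± 6.45 in WT and 3.88 ± 0.935 in DKO, and the mitotic cyclin gene Ccna2 at 26.7 ± 9.19 and 6.91 ± 0.688. Cdk1, the mitotic kinase, was at 62.6, 28.9 and 42.7 in the WT libraries and 12.4, 0.66 and 0.242 in the DKO libraries. Ccne1, the cyclin E1 gene of S phase entry, was at 19.0 ± 4.98 and 2.07 ± 2.68. By camera the cell cycle list had an adjusted p of 5.0e-17, which was 0.194 with an estimated correlation.

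Genes of the NKT1 subset and of NKT maturation were lower as a group, with 14 of 16 tested genes below 0 and a median log2 change of -1.52. Adjusted over the list alone 8 fell, and over all genes 0 passed. The chemokine receptor gene Cxcr3 was at RPKM 30.9 ± 4.50 in WT and 2.30 ± 3.23 in DKO, Cd7 was among the lowest as given above, and the chemokine gene Ccl5 was at 15.2, 4.98 and 4.90 in the WT libraries and 0.276, 0 and 0 in the DKO libraries. Klra1, an NK receptor of the Ly49 family, was at 4.76, 48.5 and 41.8 in WT and 0, 2.79 and 0.186 in DKO. The camera adjusted p was 2.7e-06, against an adjusted p of 0.0992 with an estimated correlation. Of 11 tested NKT17 genes 10 lay below 0, with a median of -0.73, and 4 fell when adjusted over the list alone (0 over all genes). They were Tmem176a at 11.01 ± 5.20 and 1.21 ± 0.622, the kinase gene Blk at 39.1 ± 28.8 and 4.65 ± 3.38, the IL-18 receptor gene Il18r1 at 14.5 ± 5.54 and 3.89 ± 1.73, and Cxcr6 at 258.5 ± 37.4 and 160.4 ± 35.2. Cxcr6 is on both the NKT1 and the NKT17 list. The camera adjusted p for NKT17 was 0.00259, and the adjusted p was 0.194 with an estimated correlation. Without DKO replicate 1 the NKT17 median was -1.22.

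The gamma-delta and NK list and the CD8 T cell list, of cells that gates on the tetramer and NK1.1 should largely remove, were also lower. These lists share genes with the NKT1 list, Klrb1c and Nkg7 among them, so the groups are not independent. The gamma-delta and NK list held 13 genes, of which 5 were tested. Of these 5 genes, 5 fell when adjusted over the list alone and 2 over all genes, with a median of -2.33. Besides Tcrg-C1 and Tcrg-C2 they were the variable segment Tcrg-V4, at RPKM 57.9 ± 11.7 in WT and 8.27 ± 6.64 in DKO, the gamma-delta transcription factor gene Sox13, at 14.1 ± 6.32 and 1.56 ± 1.80, and Klrb1c, which encodes NK1.1, with a log2 change of -2.06. Klrb1c was the only NK cell gene tested on this list, so NK cell markers were not compared as a group. Tcrg-C1, Tcrg-C2 and Tcrg-V4 belong to the same locus and are not independent. For this list camera gave an adjusted p of 6.9e-09, which was 0.0992 with an estimated correlation. On the CD8 T cell list 7 of 9 tested genes lay below 0 with a median of -1.60, and 1 fell when adjusted over the list alone (0 over all genes), the transcription factor gene Runx3, at 10.6 ± 3.83 and 1.91 ± 1.20. Nkg7 was at 17.0 ± 7.08 and 5.10 ± 3.58, and Itgae, an integrin, at 21.4 ± 13.8 and 6.00 ± 5.81. The camera adjusted p was 0.0188, and the adjusted p was 0.194 with an estimated correlation. It was 0.0905 without WT replicate 1 and 0.0861 in the 4 shallower libraries, where the median was -0.65, over a range of 0.00584 to 0.0905 across alternatives, and without DKO replicate 1 the median was -0.93.

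Glycolysis and hypoxia genes were lower, with 15 of 18 below 0 and a median of -0.45. Adjusted over the list alone 2 fell (0 over all genes), Ldha, encoding lactate dehydrogenase A, at RPKM 559 ± 58.2 in WT and 312 ± 33.9 in DKO, and the phosphoglycerate mutase gene Pgam1 at 190.1 ± 15.8 and 107 ± 19.8. Pkm and Pfkp, which encode enzymes of the same pathway, were at 327 ± 94.7 and 205 ± 43.5, and at 70.8 ± 7.91 and 43.3 ± 16.4. For glycolysis camera gave an adjusted p of 0.0370, which was 0.469 with an estimated correlation. The call was lost without WT replicate 1 (0.180), DKO replicate 1 (0.0614), DKO replicate 2 (0.0911) or DKO replicate 3 (0.0606), with array weights (0.110), without the variance trend (0.134), with a stricter filter (0.0583) and in the 4 shallower libraries (0.0976), over a range of 0.0141 to 0.180.

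Genes of naive T cells and of thymic egress were higher as a group, with 10 of 18 above 0 and a median log2 change of 0.24. Adjusted over the list alone 3 rose (0 over all genes), namely Satb1, as given above, and the GTPase genes Gimap3, at RPKM 48.8 ± 33.3 in WT and 156 ± 36.8 in DKO, and Gimap6, at 87.7 ± 11.97 and 165 ± 24.0. The IL-7 receptor gene Il7r was at 102 ± 59.2 and 233 ± 105. The egress receptor gene S1pr1 did not pass. For naive and egress genes camera gave an adjusted p of 0.00568, which was 0.194 with an estimated correlation. Without DKO replicate 1 the adjusted p was 0.0729, the highest of a range from 0.00046, and the median was -0.06, and it was 0.15 without WT replicate 2 and 0.13 without WT replicate 3.

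The list of genes induced early by T cell receptor signals was called higher by camera but was mixed, with 13 of 20 above 0, 7 below 0 and a median of 0.26. The 2 that rose when adjusted over the list alone (0 over all genes) were Cd5, at RPKM 162 ± 17.2 in WT and 276 ± 17.3 in DKO, and Cd6, at 99.3 ± 13.9 and 173 ± 10.9, which encode surface receptors that restrain receptor signalling. Nfkbia was at 25.3 ± 14.5 and 41.4 ± 8.58, Myc at 48.8 ± 4.39 and 31.4 ± 9.87, and Egr1 overlapped between the genotypes. Irf4 and Nr4a1, with log2 changes of -1.36 and -0.72, overlapped too. Fry gave an adjusted p of 0.717 for the early genes. Across them camera gave an adjusted p of 0.0351, which was 0.469 with an estimated correlation. The call was lost without WT replicate 2 (0.117), without DKO replicate 1 (0.577, median 0.05), with a stricter filter (0.0884), without the variance trend (0.0722) and in the 4 shallower libraries (0.247), over a range of 0.00995 to 0.577. The median was 0.42 without WT replicate 1, 0.09 without WT replicate 3, 0.60 without DKO replicate 2 and 0.45 without DKO replicate 3.

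Of 36 interferon response genes 24 were above 0, with a median of 0.16, and 0 passed singly by either adjustment. Ifi44 was at RPKM 0.151, 3.19 and 2.22 in the WT libraries and 10.02, 18.1 and 8.63 in the DKO libraries, and Oas2 at 19.9 ± 4.19 and 37.3 ± 9.19, while Gbp2 and Ddx58 overlapped between the groups. The camera adjusted p was 0.0017, and the adjusted p was 0.219 with an estimated correlation. Without DKO replicate 1 the median was 0.26, as also with median log2 ratio scaling, and it was 0.30 with quantile normalization. Of 46 ribosomal protein genes 40 were above 0, with a median of 0.15, and 1 fell when adjusted over the list alone, Rpl30, at 190.2 ± 25.8 and 86.7 ± 15.1, while Rps20 was at 1520.5 ± 418 and 2280.3 ± 406, and Rps24 and Rps4x did not pass. For ribosomal protein genes camera gave an adjusted p of 0.000182, which was 0.604 with an estimated correlation. The call was lost with quantile normalization (0.317, median 0.06) and without WT replicate 1 (0.1001, median 0.03), over a range of 2.0e-07 to 0.317, and the median was 0.23 without WT replicate 2 and 0.09 without DKO replicate 3.

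**Figure D3:**
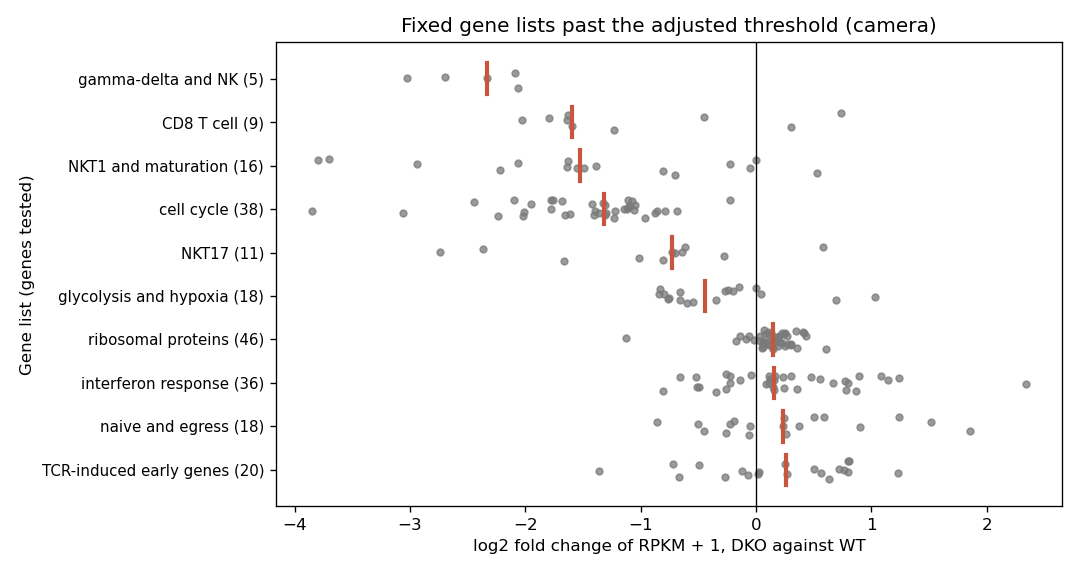
Log2 fold change of RPKM + 1 in DKO against WT (horizontal axis) for each tested gene of the 10 lists past the threshold of camera with the preset correlation, with the number of genes tested in brackets and the list median as a vertical bar. Medians run from -2.33 for gamma-delta and NK genes to 0.26 for early receptor-induced genes.

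The other 10 lists did not pass camera. NKT lineage factors had 12 genes below 0 and 11 above, with a median of 0.00, a mean of 0.01 and 0 passing by either adjustment, and Zbtb16, which encodes the NKT factor PLZF, overlapped between the genotypes. On that list Vdr, Tcf12, Myc and Ets1 had the smallest p and did not pass. NKT2 genes, with a median of -0.08 and a camera direction above 0, also gave 0 by either adjustment, with Il4ra at RPKM 1.89 ± 1.36 in WT and 7.57 ± 1.87 in DKO, Plac8 at 241.7 ± 102 and 123 ± 6.62, Lef1 at 56.9 ± 16.9 and 85.5 ± 19.8, and Pdcd1 at 145.1 ± 16.7 and 111 ± 6.33. Cytokine and chemokine receptor genes went both ways, with 4 falling and 1 rising when adjusted over the list alone (0 over all genes). Those that fell were Ccr10, at 31.9 ± 18.0 and 3.62 ± 0.883, Cxcr3, Il18r1 and Il2rb, and the 1 that rose was Tnfrsf4. Among PRC2 genes (median 0.04), which encode the complex that places the methyl marks, 0 passed by either adjustment, and Rbbp7 was at 152 ± 6.07 and 99.3 ± 10.2, Jarid2 at 9.16 ± 4.26 and 16.4 ± 2.19, and Phf1 and Phf19 overlapped between the groups. Among 13 genes of the complexes that UTX joins (median -0.12, mean -0.06, camera direction above 0), 1 rose when adjusted over the list alone, Pagr1a, from 100.6 ± 0.255 to 169 ± 8.10, while Men1, Setd1a and Dpy30 did not pass. Histone demethylase genes other than the deleted pair gave 0 by either adjustment (median -0.20, mean 0.02), with Kdm5b at 3.30 ± 0.747 and 6.82 ± 1.17 and Kdm3a, Jmjd6 and Kdm4b overlapping. Apoptosis and survival genes (median -0.16) also gave 0, with Bid at 26.9 ± 2.07 and 12.1 ± 6.38, Bik at 6.21 ± 2.78 and 0.914 ± 1.18, Birc2 at 13.2 ± 4.93 and 26.8 ± 2.08 and Birc3 at 7.02 ± 3.02 and 15.6 ± 0.73. Stress and dissociation genes, a sign of handling, gave 0 by either adjustment (median -0.06), with Hsph1, Hspd1, Hspa8 and Ddit3 having the smallest p.

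Markers of further cell types were low or mixed. Double positive thymocyte genes gave 0 by either adjustment, with a median of 0.13 and a mean of -0.12, and Tcf12, Cd1d1, Mns1 and Aqp11, with the smallest p, overlapped between the genotypes. Of 6 tested myeloid and dendritic genes 2 rose and 2 fell when adjusted over the list alone (0 over all genes). Those that rose were the MHC class II genes H2-Aa and Cd74. H2-Aa was at RPKM 1.34 ± 0.917 in WT and 10.01 ± 5.03 in DKO. Cd74 was at 5.82 ± 2.01 and 26.0 ± 17.3, and its values overlapped between the genotypes. H2-Ab1, another MHC class II gene on the list, overlapped too and did not pass by either adjustment. It was at 9.644, 4.804 and 0.168 in WT and 13.68, 4.194 and 0.658 in DKO (log2 change 0.269). MHC class II genes thus did not all rise. Those that fell were Fcer1g, at 2.90, 12.04 and 11.8 in WT and 0.096, 0 and 0 in DKO, and Cd68, at 8.85, 5.83 and 4.26 in WT and 0, 0 and 3.08 in DKO. Lists with fewer than 5 genes tested were not compared. The table listed 0 of 13 B cell genes, 2 of 16 thymic stroma genes (Pecam1 at 18.9 ± 13.0 and 15.4 ± 12.7, Ccl25 at 6.64, 6.81 and 4.97 in WT and 9.73, 0 and 11.2 in DKO) and 1 of 11 erythroid genes (Hba-a2, at 0.118, 1.06 and 0 in WT and 21.1, 0 and 3.27 in DKO). It listed 1 of 44 classical Polycomb targets, Cdkn1c, at 0, 1.65 and 7.02 in WT and 0, 1.38 and 9.86 in DKO. Of 4 tested regulatory T cell genes Tnfrsf4 rose and Capg fell when adjusted over the list alone, Capg from 215 ± 18.5 to 95.1 ± 34.7, and Nrp1 and Tnfrsf18 overlapped. Igkc, an immunoglobulin gene that is on none of these lists, was at 14.5, 9.41 and 0.615 in WT and 43.2, 94.0 and 1.92 in DKO and did not pass for genotype. The X-linked genes Eif2s3x and Ddx3x, kept for the check of sex labels, overlapped between the genotypes.

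The second comparison was between 4 female and 2 male libraries, with genotype in the model. Klk1b22, a kallikrein-type protease gene, was the 1 gene past the adjusted threshold (limma, adjusted p = 0.0279), listed at 0 in both male libraries and at RPKM 42.7, 24.2, 26.2 and 18.7 in the female ones. Next in rank and not passing was Igkc, the immunoglobulin kappa constant gene, at 14.5, 9.41, 43.2 and 94.0 in the female libraries and 0.615 and 1.92 in the male ones. Snord14a, Trav6-4, Stk25 and Ly6d followed in that order, lower in both male libraries than in each female library and did not pass, with Stk25 at 26.3, 30.7, 8.32 and 41.2 in the female libraries and 2.82 and 0.076 in the male ones, and Ly6d at 39.1, 4.27, 14.2 and 15.2 against 0 and 0. At an unadjusted p of 0.05 there were 376 genes, against about 535 by chance. Each genotype held 1 male library, replicate 3 in both, so sex cannot be told apart from replicate number. The filter asked for RPKM of at least 1 in at least 3 libraries, so genes seen only in the 2 male libraries could not be tested. The Y-linked gene Eif2s3y was left out in this way.

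The last comparison asked whether the genotype difference differed with sex, since Kdm6a is X-linked and has a Y-linked relative. In the limma model with 2 residual degrees of freedom 0 of 10694 genes passed, with 293 at an unadjusted p of 0.05. The smallest p belonged to Trbj1-2, a beta joining segment, at RPKM 14.2, 25.9 and 57.9 in WT and 42.4, 50.03 and 3.23 in DKO (adjusted p = 0.9997). Nme3, Snora3 and the row ENSMUSG00000064681 followed, each with a low value in the male DKO library, of 8.87, 0 and 0. With 1 male library per genotype such a value cannot be separated from that library.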

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

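The 4 shallower libraries, voom and thinning were chosen after seeing the data. The alternative planned for a table of counts was not run, since the unit is RPKM. With 23 alternatives, the calls for the 106 named genes were the same in 2306 of 2426 cases, lost in 76, gained in 29 and of opposite direction in 15, and for the 20 lists the same in 414 of 458, lost in 18, gained in 1 and of opposite direction in 25. The lists cell cycle, gamma-delta and NK, NKT1 and maturation, NKT17 and interferon response kept their direction and their side of the threshold under each of these alternatives run for them with camera's preset correlation (22 for gamma-delta and NK, which, like the myeloid list, the stricter filter left with fewer than 5 genes), while none of the 20 lists passed with an estimated correlation and fry did not call cell cycle, NKT17 or interferon response. Fewer libraries leave the adjusted test less power, and no other cause was tested for the calls below. Against 9 genes, 24 were called with array weights, 0 with the female libraries only, 0 with voom and 1 (S100a6) in the 4 shallower libraries, and leaving out single libraries gave 0 to 13. Without the variance trend 11 genes were called, sharing 1 (Amigo2) with the 9. By size and no overlap (719 genes), the female libraries gave 1431, the 4 shallower libraries 1423, and leaving out single libraries 898 to 1274. Smaller groups more often fail to overlap by chance, so these counts cannot be compared with 719. Sex gave 1 gene, and 2 (Klk1b22 and Eif2s3y) without a filter. With the replicate number as a block 9 genes were called, 8 of them shared, Satb1 gained and Amigo2 lost. The deviations of same-numbered libraries correlated across genes at 0.226, 0.146 and 0.075, not all above 0.1. Each library correlated best with its own number, a hint of pairing. The deposited column names give replicate 1 of both genotypes a shared set label (Set1), whose meaning is not stated. Whether the numbers mark pairs or batches is not stated either, and the main model ignored them.

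The direction turned only for genes and lists that had not passed. Leaving out single libraries moved the log2 change of Kdm6a from -0.312 to 0.415, Cdkn1c from -0.844 to 0.877, Pecam1 from -1.131 to 0.301, Ccl25 from -1.113 to 0.690, Tnfrsf18 from -0.095 to 0.434 and Ddx3x from -0.22 to 0.926. It moved the median of NKT lineage factors from -0.163 to 0.184, NKT2 from -0.311 to 0.021, receptors from -0.367 to -0.007, UTX partners from -0.321 to -0.040, apoptosis from -0.258 to -0.005, stress from -0.213 to 0.229, double positive thymocytes from -0.721 to 0.656 and myeloid genes from -0.586 to 0.388. The double positive list passed without WT replicate 1 (median 0.649, camera adjusted p = 0.0114). In female libraries Kdm6a was at -0.167, Cdkn1c at -0.077, Ddx3x at -0.248, apoptosis at -0.008 and myeloid genes at -0.144. With voom Kdm6a was at -0.173, Ddx3x at -0.087, NKT2 at -0.091 and apoptosis at -0.217. In the 4 shallower libraries Tnfrsf18 was at -0.128 and receptors at -0.218. With array weights Cdkn1c was at -0.219 and myeloid genes at 0.154, and apoptosis was at -0.164 without the trend. Myeloid genes were at 0.11 with a pseudocount of 0.1, at -0.055 with sex as covariate, at -0.055 with the replicate block and at 0.033 with thinning. For lists, the direction is camera's, which can differ from the sign of the median.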

Other observations

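The tests of shared reads, gamma-delta cells, thinning and scaling were chosen after the results they bear on were seen, and what the other splits would show was written down after their counts had been seen. What matched lists and highly expressed genes would show was written before those values were computed. The families described first were chosen after their values were seen. Of 41 tested histone genes of the Hist1h cluster, chosen by name alone, 38 had a log2 change below 0. The median was -1.30 (-1.39, -1.03 and -1.20 with a fixed sum, quantile normalization and median scaling). In 21 of the 41 the groups did not overlap in that direction, 0 passed the adjusted threshold, and the family had no test of its own. Hist1h3a was at RPKM 13.1, 12.4 and 7.06 in WT and 0.49, 0.265 and 0.581 in DKO. Members of the cluster resemble each other, so reads may be shared between them. How well an amplification of polyadenylated RNA captures histone transcripts was not tested. The CD3 chains and the alpha-beta receptor genes of NKT cells did not pass. Trbc1 and Trbc2 had log2 changes of -0.01 ± 0.20 and 0.07 ± 0.20 (SE), Trac was at 0.65 ± 0.18 and the joining segment Traj18 at 0.38 ± 0.21. Thy1, a surface marker of T cells, was at 149, 269.9 and 202.1 in WT and 38.5, 0.732 and 41.7 in DKO (log2 change -3.82, not passing). Without DKO replicate 2 the log2 change was -2.30, and Thy1 then passed.

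Gamma locus genes were lower in DKO. Sharing of reads between gamma gene copies would leave their sum unchanged, but reads per 1 M summed over the 10 rows changed by -2.32 log2 units with no overlap, so it does not account for the fall. Gamma-delta T cells among the sorted WT cells may be another source, since Sox13 was also lower, as was Cd163l1, at RPKM 18.5, 14.997 and 23.9 in WT and 0.868, 0 and 2.54 in DKO, although a tetramer gate would remove most such cells. They would dilute the alpha-beta constant genes in WT. The mean log2 difference of Trac, Trbc1 and Trbc2 was 0.24, with a 95% interval from -0.06 to 0.54, too wide to decide. That mean joins unlike genes, since Trac was higher in DKO while Trbc1 and Trbc2 hardly changed, as given above. Trdc, the delta constant gene on the gamma-delta list, had no row in the table. A change of gamma transcription within NKT cells, by genotype, stays open and was not tested.

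Cell cycle genes were lower in DKO. Depth does not account for it, since implied totals were already similar between the genotypes at each replicate number. Thinning all libraries to an implied total of 5.0 M reads could therefore change little, and the median log2 change was then -1.31. Such thinning does not match library complexity. A general loss of transcripts of like level and length is argued against too. Of 10000 random lists matched on mean level and gene length, 0 had a median as low as -1.32, the lowest being -0.54. Random genes need not vary together as the cell cycle genes did (estimated correlation 0.384), so the spread of those medians may be too narrow. Camera's p for the list was 2.5e-18 between the genotypes but also 1.9e-15 with WT replicates 1 and 2 and DKO replicate 1 set against the rest. That p lay under 0.05 in 7 of the 9 other splits. Since each other split keeps part of any genotype difference, this does not decide. A smaller share of dividing cells in the DKO fraction is a candidate explanation that remains open, as does a mixture of cells that differ in division, and neither was tested.

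More genes were lower than higher in DKO, 74.0% of those by size and no overlap. Loss of weak transcripts would act on low genes. Among genes with a mean RPKM of at least 50 the share was 89.4% (59 lower and 7 higher). Such loss thus does not account for the excess among those genes. Most genes in the count had a mean RPKM under 50, with 473 lower and 180 higher (72.4%), and among them it cannot be excluded. Scaling may contribute and cannot be told apart from a true shift, because the share was 55.4% with quantile normalization and 61.6% with median log2 ratio scaling. DKO libraries also held more genes listed at 0, with 192, 329 and 237 after thinning to equal implied totals against 112, 37 and 88 in WT, a step that does not match library complexity. An effect of genotype stays open and was not tested.

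The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes past the threshold, 1 of the 10 splits, the real one, gave as many as 9, and the highest other split gave 1. For lists it was 1 of 10, with 10 lists and 5 in the highest other split. For genes by size and no overlap it was 1 of 10, with 719 and 457. Median SD between libraries was 0.50 in DKO and 0.37 in WT on the log2 scale, and 0.29 and 0.27 for genes with a mean RPKM of at least 50. On the first principal component (33.9% of variance) WT replicates 1 to 3 lay at -42.8, -16 and -22.3 and DKO replicates 1 to 3 at -6.3, 79.2 and 8.1, so on it the genotypes did not overlap and DKO replicate 2 lay farthest from the rest. On the second (23.1%) and the following one (22.3%) the genotypes overlapped, and DKO replicate 3 (-68.7) and DKO replicate 1 (65.8) lay farthest.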
